A study of Mus musculus with 10 samples.

How the data were processed

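The series profiled binding of HA-tagged HNF4A by chromatin immunoprecipitation and sequencing (ChIP-seq) with an anti-HA antibody. The cells were 2 mouse pancreatic ductal adenocarcinoma (PDAC) lines, HC800a8-1 and HC569a8-18, called HC800 and HC569 here. Per the labels, cells received doxycycline at 1 mg per ml or vehicle for 7 days, and HNF4A status was positive with doxycycline and negative without it. The series has 10 samples. Of these, 6 are ChIP libraries: in each line, 1 vehicle control and 2 doxycycline replicates. The other 4 samples are inputs, which entered only through the peak calls of the authors and were not analysed here on their own. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. The bracketed identifiers in the titles share one prefix in the replicate 1, control and input libraries and another in both replicate 2 libraries, and whether the prefix marks a batch is not stated.

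Per the submitters' processing notes, reads were aligned to mm10 with Bowtie 1.1.2 and peaks were called with MACS2 2.1.0.20140616. Per the file headers, peaks were called for each ChIP library separately against 1 input, with a p-value cutoff of 1e-10. The other settings per the file headers were an mfold range of 15 to 100, 1 tag kept per position, an effective genome of 2.7 Gb, local background ranges of 1 kb and 10 kb, and scaling of the larger library towards the smaller. Both doxycycline replicates of a line were called against the same input. The deposited pileup is a coverage signal, the height of extended tags at the summit. The deposited fold enrichment is a linear ratio of pileup to local background, with 1 added to each. The deposited p-values and q-values are given as −log10 values. Fold, p and q per peak are the authors' own values for that peak and were used only to describe, rank or filter peaks within their list.

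Tags kept after duplicate removal, per the file headers, set the precision of each list. The doxycycline ChIP libraries held between 15.9 and 30.4 M tags (M for mega) and their inputs 31.3 M in HC800 and 30.2 M in HC569. The control ChIP libraries held 32.4 M tags in HC800 and 22.1 M in HC569, but their inputs held 0.649 and 5.30 M. As the larger library was scaled down, the controls were called at the depth of those inputs. To state what that depth allows, the Poisson p-value was computed again for each doxycycline peak, and peaks still at or under 1e-10 were counted. Pileup and local background were scaled to the control's effective tag number and also by the ratio of its fragment length to that of the doxycycline library. The background was kept at or above the genome background of the control. The same calculation at the deposited depth differed from the deposited −log10 p by at most 0.000157 in the doxycycline lists, over peaks with −log10 p under 250.

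Peaks of the 4 doxycycline lists were merged into regions where they overlapped by 1 bp or more. A region was called shared when it held a peak of all 4 lists. It was called HC800-only or HC569-only when both replicates of that line and neither of the other had a peak in it. Overlaps and locations were set against 100 random placements of the same peaks on their chromosomes, between the first and last annotated gene. The smallest 2-sided permutation p these allow is 0.0198. Shares of peaks carry 95% Wilson intervals, or an exact binomial interval for shares at control depth, which cover counting error only. Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. That table holds gene starts and ends without strand, exons or transcripts, so a location within 1 kb of either gene end stands in for a transcription start site, and the gene body for exons and introns. No genome sequence was used here, so the planned motif counts were not run.

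A gene was near a region when its body held the summit or was nearest to it within 50 kb. Occupancy of 15 gene lists, with 379 entries that all matched the gene table, was compared with 10000 random lists of equal size, matched on deciles of the stretch of genome for which a gene is nearest. The smallest 2-sided p these allow is 0.0002. The difference between lines was tested as genes near HC800-only minus genes near HC569-only regions in the same random lists. Benjamini-Hochberg adjustment ran over the 15 lists within each set of regions, with a threshold of 0.05. Local input was taken from the deposited fold and pileup of the replicate 1 lists, as both replicates of a line had the same input. Its log2 at shared regions, less the median of the list, was averaged in windows of 10 Mb with at least 20 shared regions, and set as HC800 minus HC569. Line-only regions per window were compared as a log2 ratio with 0.5 added to each count, and its correlation was tested with 100000 permutations.

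Named genes followed a rule fixed before the data were examined. It took up to 4 members of each list with the best mean rank of their strongest peak by q, the 10 shared regions with the best mean rank by fold, and the 5 best HC800-only and 5 best HC569-only regions by q. It also took 14 fixed genes, among them Hnf4a, Hnf1a, Six1, Foxa1 and Cdh1, and every control peak. Genes named outside it are said to be so where they appear.

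The alternatives were thresholds of 5 and 10 on −log10 q and of 10 on fold, summits within 100 bp, a reciprocal overlap of 50%, equal peak numbers per list, other gene windows and annotations, unmatched random lists, leaving out each replicate number, and counting line-only regions within replicate numbers. For region counts, the last of these repeats the one before it. The threshold of 5 removed no peak. Some were chosen after seeing the data: lists recomputed at the tag number of the smallest doxycycline ChIP library, regions more than 1 kb from a gene end, random lists matched also on window input, and crossed replicate numbers. The overlap, region and list procedures were tested on simulated data. Lists with no excess were called in 3.0% of simulations on shared regions. Lists of 25 genes with occupancy raised or lowered by 0.3 were called in 85.5% and 87.0%. Lists without a difference were called in 1.5%. Lists set to exactly 5 genes against 0 were called in 100% of cases, which their construction fixed and which is no measure of power. Calls in the list simulations used an unadjusted p under 0.05 for a single list, so these shares are not those of the adjusted tests. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.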

Results

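Binding of HA-tagged HNF4A, a nuclear receptor that sets gene programmes of liver, gut and pancreas, was mapped in 2 mouse PDAC lines. Each line contributed 1 vehicle control and 2 doxycycline ChIP libraries. The doxycycline libraries held 15.9 and 30.4 M tags in HC800 (replicates 1 and 2) and 19.0 and 16.2 M in HC569. Coordinates are mm10. Fold values of peaks are the authors' own and are given as the range over the 4 doxycycline lists, in which replicates were called separately. Outside the line-only comparisons, a range given for a gene takes its strongest peak by q in each list. These peaks can lie at different sites in different lists, so the range need not be that of the shared regions.

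The first comparison asks which sites carried HA signal with and without induction. With doxycycline, HC800 gave 26320 and 24975 peaks and HC569 gave 29049 and 22576. Without it, HC800 gave 0 peaks and HC569 gave 1. By mean rank of fold over the 4 doxycycline lists, the leading induced site lay in Mia2 on chromosome 12 (59130641 to 59131792, 45 to 81.2). Mia2 is a cargo receptor gene of the endoplasmic reticulum. After it came a site 4.49 kb from Fblim1 on chromosome 4 (47.2 to 75.6). Next came a site at a gene end of Mov10 on chromosome 3 (51.8 to 79.1), which encodes an RNA helicase, a site in Fgf18 on chromosome 11 (43.5 to 83.3), a growth factor gene, and one 32.5 kb from Spag9 (40.4 to 88.1). Lpar1, Ran, Sepsecs and Pink1 had sites of this group within 1 kb of a gene end, and Skor1 had one at 28.8 kb. The highest fold among these 10 regions was 97.4, beside Ran in HC800 replicate 1.

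The 1 control peak was in HC569, on chromosome 3 (5860592 to 5860808), 282 kb from the nearest protein-coding gene, Pex2. Its fold was 7.39 in the control. A peak overlapped it in each of the 4 doxycycline lists, with folds of 4.66 and 2.42 in HC800 and 6.32 and 7.71 in HC569. With 1 control per line the difference between control and doxycycline has no replicate check. The controls were also called at low effective depth. Scaled to the tag number and fragment length of the HC800 control, 74 of 26320 peaks of HC800 replicate 1 (0.281%, exact binomial interval 0.221 to 0.353) and 0 of 24975 of replicate 2 would pass the cutoff. The fragment length was 110 bp in that control, against 176 and 169 bp in replicates 1 and 2. Scaling by tag number alone, which was not counted, would let at least as many pass. Absence of HC800 control peaks was thus not measurable at this depth and fragment length. Scaled likewise to the HC569 control, 8628 of 29049 peaks (29.7%) and 7770 of 22576 (34.4%) would pass.

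**Figure D1:**
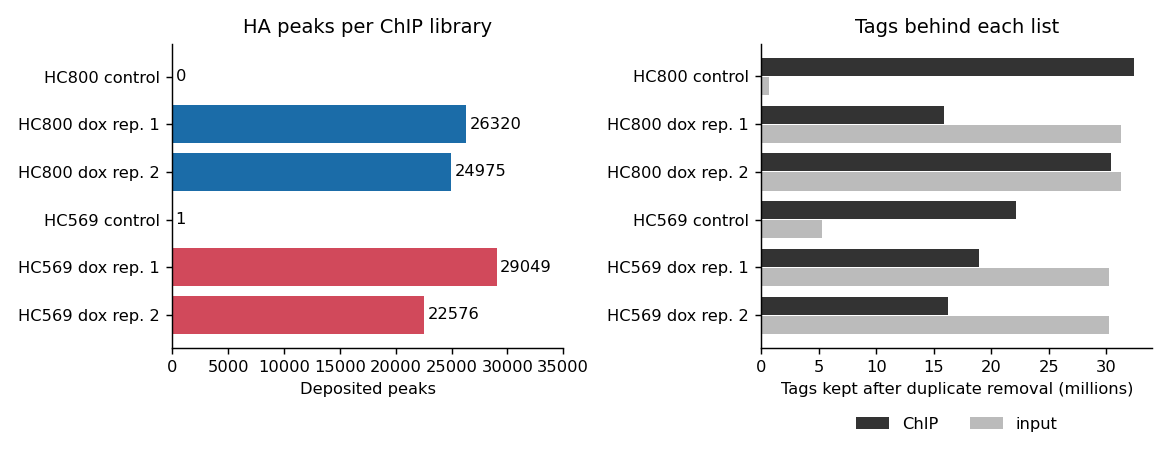
Left, number of deposited peaks in each of the 6 ChIP libraries (blue HC800, red HC569); right, tags kept for the ChIP and its input, in M. The controls have 0 and 1 peaks, and their inputs hold 0.649 and 5.30 M tags.

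The second comparison asks how far replicates of a line found the same sites. Of HC800 replicate 1 peaks, 61.9% overlapped a peak of replicate 2, and 69.5% in the other direction. In HC569 the shares were 68.4% of replicate 1 and 86.8% of replicate 2. Random placements gave about 1% (highest of 100 placements 1.28% for HC569 replicate 2), and each permutation p was 0.0198, the smallest possible. The strongest peaks by q were found again most often: of the top decile of each list at least 92.4% overlapped the other replicate, against 16.5% to 58.0% of the bottom decile. Over the 13208 regions called in all 4 lists, the rank correlation of fold was 0.61 between the HC800 replicates and 0.76 between the HC569 replicates, computed across regions, which are not independent replicates. In HC800, overlap with the other line was the higher in 3 of 4 comparisons: 67.9% and 65.5% of replicate 1 peaks overlapped HC569 replicates 1 and 2, against 61.9% within the line, and 78.6% and 69.2% of replicate 2 peaks did, against 69.5%. In HC569 it was the lower in all 4, at 63.8% and 66.2% of replicate 1 peaks and 78.0% and 73.7% of replicate 2 peaks.

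The third comparison asks which sites the lines share. Merging gave 40183 regions, of which 13208 (32.9%) were called in all 4 lists and 15072 (37.5%) in a single list. Of the regions called in both HC800 replicates, 84.6% were also called in both HC569 replicates, and the reverse share was 71.6%. HC800-only regions numbered 959 and HC569-only regions 1711. The leading HC800-only regions by q lay 71.4 kb from 1600014C23Rik on chromosome 17 (folds 16.2 and 32.9 in the 2 HC800 lists), 2.56 kb from Meis1, a homeobox gene, on chromosome 11 (21.4 and 36.9), 80.6 kb from Rai14, in Gse1, and at a gene end of Ncam1, a neural adhesion molecule gene (17.8 and 21.6). The leading HC569-only regions lay at a gene end of Degs2, a sphingolipid enzyme gene, on chromosome 12 (28.1 and 29.6), in Foxp1, a forkhead factor gene (28.2 and 34.3), 35.8 kb from Msrb3 (37.1 and 38.2), in Nckap5 (35.2 and 40.4) and in Zfp568 (27.7 and 37.8).

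The number of line-only regions, 2670, was not the highest among the 3 ways to split the 4 lists into pairs. Pairing HC800 replicate 1 with HC569 replicate 2 against the rest gave 2982, and pairing by replicate number gave 1270. With 3 splits no share under 0.05 is possible. Requiring a single replicate per line raised the counts to 7321 HC800-only and 5536 HC569-only regions without replicate 1, and to 8265 and 10235 without replicate 2. At a common tag number, an alternative chosen after seeing the data, HC800-only regions fell to 596 and HC569-only regions rose to 1897.

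Line-only regions also differed along the genome. On chromosome 10, 11 regions were HC800-only and 117 HC569-only, and on chromosome 9 the counts were 110 and 54. Over 199 windows of 10 Mb, the log2 ratio of HC800-only to HC569-only regions rose with the log2 difference in local input level between the lines (Pearson r = 0.72, Spearman rho = 0.73, each with permutation p = 1e-05, the smallest possible; r = 0.71 without the 2 windows farthest from the median). Windows of one chromosome are not independent. In the 90 windows with input within 0.2 (log2) of balance, 492 regions were HC800-only and 625 HC569-only.

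**Figure D2:**
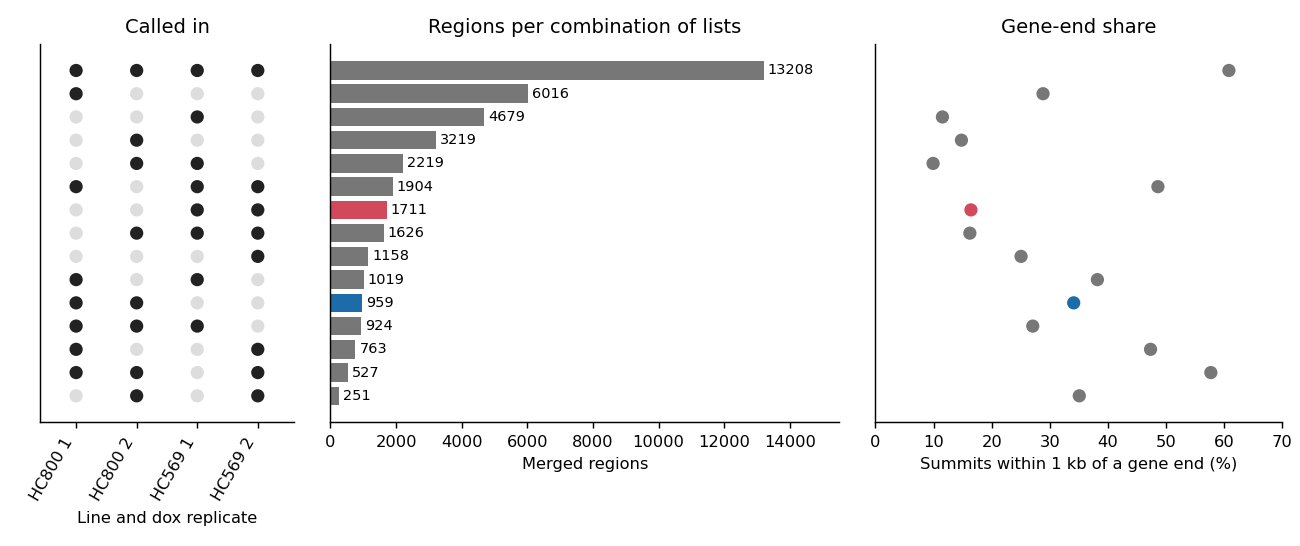
Merged regions by the combination of doxycycline lists that called them (filled circles, left), their number (middle) and the percent of summits within 1 kb of a gene end (right). The 13208 regions of all 4 lists have a gene-end share of 60.8%; HC800-only regions are blue and HC569-only regions red.

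**Figure D3:**
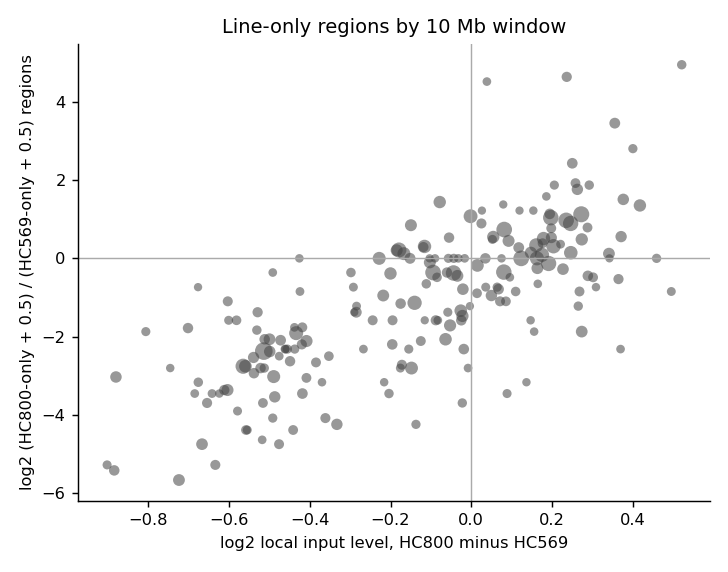
Each point is a 10 Mb window, larger with more shared regions; the x axis is the log2 local input level of HC800 minus HC569 and the y axis the log2 ratio of HC800-only to HC569-only regions with 0.5 added to each. The 199 windows rise together with r = 0.72.

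The fourth comparison asks where in the genome the sites lie. Shared regions sat at genes: 60.8% of summits (Wilson interval 59.95 to 61.6) were within 1 kb of a protein-coding gene end, against 3.25% of random placements, and 73.2% were inside a gene body, against 41.3%. At a distance over 50 kb from any gene body lay 1.98%, against 34.4%. HC800-only regions had a gene-end share of 34.1% and HC569-only regions 16.4%, both above their random means of 3.31% and 3.22%. Each permutation p against placement was 0.0198, the smallest possible. Between the line-only sets the gene-end share differed in a Fisher's exact test over regions, which are not independent replicates (odds ratio 2.63, p = 1.12e-24). That direction depended on the replicate: without replicate 1 the shares were 17.4% for HC800-only and 33.5% for HC569-only regions (odds ratio 0.417), and without replicate 2 they were 33.0% and 12.7% (odds ratio 3.37).

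The fifth comparison asks which gene groups lie near HNF4A sites common to both lines. Of 21887 protein-coding genes, 9562 (43.7%) were near a shared region. Random lists were not matched on gene activity, which was not measured here. Occupancy above or below them therefore cannot be assigned to the function of a list. Genes of epithelial junctions and keratins were occupied more often than matched random lists, with 21 of 25 near a shared region against a random mean of 10.8 (adjusted permutation p = 0.00075). Their strongest peaks were at Krt18 (28.5 to 52.3) and Krt8 (18.5 to 35.0), the keratin pair of simple epithelia, Jup (21.7 to 41.2), a junction plaque protein gene, and Crb3 (15.2 to 32.2), a polarity gene. Cdh1, encoding E-cadherin, had 2 shared regions. Its strongest peaks (13.4 to 18.4) lay at different sites, some at a site without a peak in HC800 replicate 1. In its shared regions, HC800 replicate 2 had folds of 5.41 to 5.64. Fatty acid and lipid genes followed with 23 of 30 against 13.0 (adjusted permutation p = 0.00075), led by Scd1 (21.7 to 45.7), a fatty acid desaturase gene, Acadm (28.3 to 39.6) and Hadhb (25.5 to 47.7), which encode enzymes of fatty acid oxidation, and Dgat2 (18.0 to 44.9), a triglyceride synthesis gene. Cell cycle genes were near a shared region in 20 of 29 cases against 12.5 (adjusted permutation p = 0.0131), with Mcm7 (19.3 to 47.9), Rbl1 (18.3 to 38.3), Ccnd1 (14.2 to 31.6) and Cdkn1b (11 to 27.8) at the top.

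Over all shared regions, 7 lists were occupied less often than random lists, which were not matched on gene activity. Of liver plasma protein and hepatocyte metabolism genes, 6 of 34 were near a shared region against 14.5 (adjusted permutation p = 0.0111). Proc, encoding the anticoagulant protein C, was a strongly bound member with 3 shared regions (25.5 to 76.6), and Apob (10.5 to 28.0) and Trf (7.56 to 37.1) had 1 each, while Apoc2 had peaks in 3 lists and no shared region. Of intestinal genes, 6 of 30 were occupied against 13.3 (adjusted permutation p = 0.0183; over shared regions more than 1 kb from a gene end 5 against 4.58, adjusted permutation p = 1.0), among them Cdx2, an intestinal homeobox gene with 5 shared regions (22.4 to 45.4), Vil1 with 3 (14.3 to 32.9), Anpep and Gpa33. Gastric and foregut genes had 1 of 23 against 9.90 (adjusted permutation p = 0.00075), which was Aqp5 (6.67 to 10.9); Psca, Agr2 and Capn8 had peaks without a shared region. Genes of the classical PDAC subtype had 3 of 23 against 10.1 (adjusted permutation p = 0.0072), namely Oit1 (14.9 to 23.3), Prr15l (6.79 to 14.5) and Lgals4 (4.2 to 15.3). Acinar genes had 1 of 22 against 9.22 (adjusted permutation p = 0.00075), the protease gene Ctrb1 (8.0 to 16.6). Lists of other cell types were low as well, with 3 of 24 immune genes against 10.3 (adjusted permutation p = 0.0080; Spi1, Cd14 and Prf1) and 5 of 22 neuronal genes against 10.3 (adjusted permutation p = 0.0477; Snap25 and Grin1 among them).

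The remaining lists did not pass. Endodermal transcription factors had 19 of 29 against 13.3 (adjusted permutation p = 0.0744) but passed under 5 of 10 alternatives (adjusted permutation p from 0.0065 to 0.186), with Gata4 (26.0 to 63.5), Gata5 (11.2 to 56.9), Ppara (20.2 to 47.8) and Hnf1a (15.9 to 34.4) strongest. Foxa1 had 1 shared region, with folds of 5.01 to 15.4. Its strongest peaks reached 41.0 at another site, which had no peak in HC800 replicate 2. Foxa2 had 3 shared regions, Gata6 had 2 and Foxa3 had 0. Ductal genes had 10 of 18 against 8.58 (adjusted permutation p = 0.770), led by Car2 (19.3 to 47.0) and Aqp1 (13.4 to 37.2), with Hnf1b at 5 shared regions (11.5 to 19.9). Six1-type and other mesodermal factors had 10 of 20 against 9.14 (adjusted permutation p = 0.924), led by Osr2 (15.2 to 37.5), Meox1 and Foxc1. Six1 had 2 shared regions (7.97 to 19.7). Six4 had 0 shared and 1 HC800-only, but had peaks in all 4 lists (6.64 to 12.8). Mesenchymal and EMT genes had 12 of 26 against 11.6 (adjusted permutation p = 1.0), with Snai1 at 4 shared regions (12 to 44.4), Fn1, Mmp14, Col1a1, Zeb1 at 3 and Vim at 1. Basal-like PDAC genes had 6 of 24 against 10.3 (adjusted permutation p = 0.149), with Cst6, Tns4, Dhrs9 and Slc2a1 strongest.

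**Figure D4:**
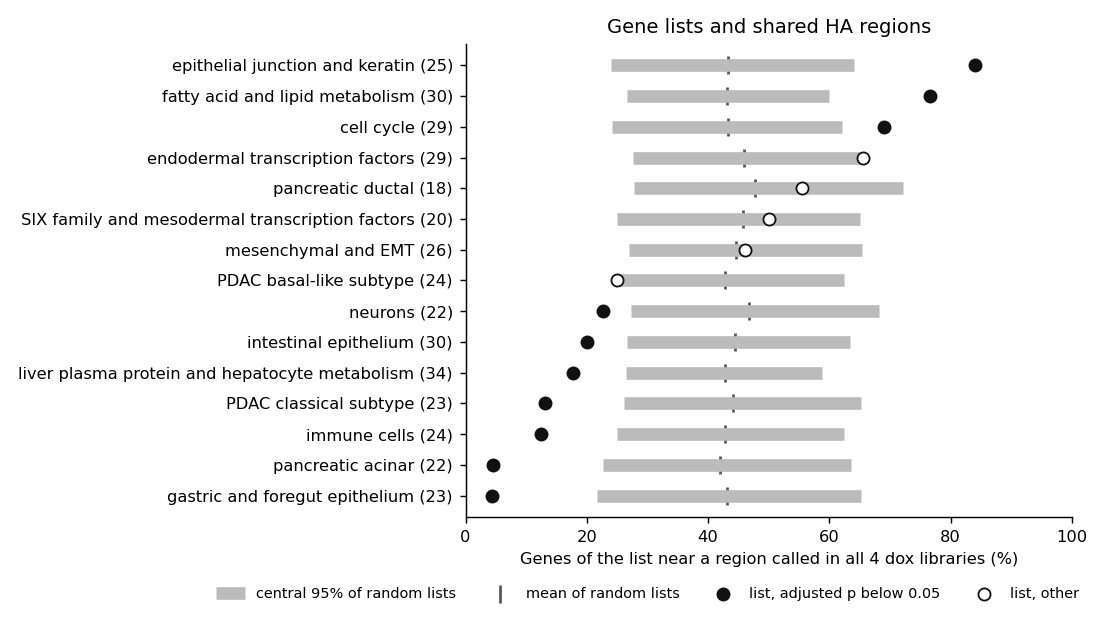
Percent of each gene list (size in parentheses) near a region called in all 4 doxycycline libraries; grey bars span the central 95% of 10000 matched random lists with their mean as a tick, and filled points passed the adjusted threshold. Epithelial junction and keratin genes stand highest and gastric and acinar genes lowest.

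Over shared regions more than 1 kb from a gene end, an alternative chosen after seeing the data, 2 lists passed, both high: epithelial junction and keratin genes (14 of 25 against 3.61, adjusted permutation p = 0.0030) and endodermal transcription factors (13 of 29 against 5.09, adjusted permutation p = 0.0075). Counts were smaller there and none of the low lists passed, but apart from the intestinal list they stayed below their random means, with 2 liver genes against 4.32, 0 gastric against 3.07, 1 classical subtype against 3.36, 0 acinar against 2.61, 1 immune against 3.20 and 2 neuronal against 4.34, while fatty acid and lipid genes (7 against 4.31) and cell cycle genes (9 against 3.82) stayed above. The neuronal list lost its call under 6 of 10 alternatives and the cell cycle list under 3 of 10.

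The sixth comparison asks which gene groups lie near the regions of only one line. HC569-only regions lay near 8 of 29 endodermal transcription factors against a random mean of 2.19 (adjusted permutation p = 0.0270). These were Gata4 with 4 regions, Foxa2 with 2 and, named after their values were seen, Elf3 with 3, Klf4, Nr0b2, Nr5a2, Onecut2 and Pdx1, and the list passed under 10 of 10 alternatives. It also passed for HC800-only regions when a replicate number was left out in both lines (13 against 6.42 without replicate 1, adjusted permutation p = 0.0457, and 14 against 7.28 without replicate 2, adjusted permutation p = 0.0435), 2 of 10 alternatives with adjusted permutation p from 0.0435 to 1.0. HC569-only regions also lay near 6 of 25 epithelial junction and keratin genes against 1.48 (adjusted permutation p = 0.0375): Jup and, named after their values were seen, the tight junction genes Tjp1, Tjp2 and Tjp3 (up to 21.3 in fold), the desmosome gene Dsp and the splicing regulator Esrp2. This call ended under 6 of 10 alternatives (adjusted permutation p from 0.0015 to 0.408), although with matching on input it stood at 6 against 1.64 (adjusted permutation p = 0.0825) and at a common tag number at 6 against 1.64 (adjusted permutation p = 0.0690). The windows of Tjp1, Tjp2 and Tjp3 had lower local input in HC800 than in HC569 (log2 differences of −0.48, −0.44 and −0.56), while those of Dsp, Esrp2 and Jup stood at −0.19, −0.03 and +0.23. For HC800-only regions 0 of 15 lists passed and 2 had an unadjusted permutation p under 0.05, the mesenchymal and EMT list (5 of 26 against 1.05, p = 0.0082) and the Six1-type and mesodermal list (4 of 20 against 0.943, p = 0.0276).

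In the test of the difference itself, mesenchymal and EMT genes leaned to HC800 (5 near HC800-only and 0 near HC569-only regions, adjusted permutation p = 0.0165) and epithelial junction and keratin genes to HC569 (0 and 6, adjusted permutation p = 0.0165). The 5 EMT genes were the transcription factor genes Snai1 and Zeb1 and, named after their values were seen, Zeb2, Twist1 and Twist2, with folds of 4.19 to 16.8. Snai1, Zeb1, Zeb2 and Twist2 also held 4, 3, 2 and 2 shared regions, and Twist1 had a peak in HC569 replicate 2 (8.43). The epithelial genes Tjp1, Tjp2, Tjp3, Dsp, Jup and Esrp2 held 1 to 4 shared regions each. Both differences thus concern further regions at genes with peaks in both lines. The endodermal factors did not pass (3 and 8, adjusted permutation p = 0.168) but did with equal peak numbers (difference −8, adjusted permutation p = 0.0030) and at a common tag number (−8, adjusted permutation p = 0.0150), 2 of 10 alternatives with adjusted permutation p from 0.0030 to 0.989. Leaving out a replicate number in both lines ended the EMT call in each case and the epithelial call in one. Without replicate 1 the differences were +5 for EMT and +5 for epithelial genes (adjusted permutation p = 0.545 for each), and without replicate 2 they were +2 (adjusted permutation p = 0.527) and −11 (adjusted permutation p = 0.0030). Over 10 alternatives the adjusted permutation p ran from 0.0075 to 0.545 for EMT genes, whose call also ended within 10 kb and over regions more than 1 kb from a gene end, and from 0.0030 to 0.545 for epithelial genes, whose call also ended with equal peak numbers. Splitting the 4 lists crosswise, HC800 replicate 1 with HC569 replicate 2 against the rest, also gave 2 lists past the threshold, as many as the split by line. The epithelial list was among them again (0 and 7 genes, adjusted permutation p = 0.0105), beside fatty acid and lipid genes. EMT genes passed only in the split by line.

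The Hnf4a gene itself, on chromosome 2 (163506811 to 163572907), held 5 shared regions, with folds of 4.35 to 11.7 at its strongest peaks. Local input there was above that of other peaks of the chromosome. At peaks inside the gene its median was 14.2 and 16.9 times the genome background in HC800 and 6.45 and 6.01 times in HC569, against 3.43, 3.58, 2.5 and 2.58 at all chromosome 2 peaks of the same lists. Hnf4g, the paralogue, had 0 peaks in any list.

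**Figure D5:**
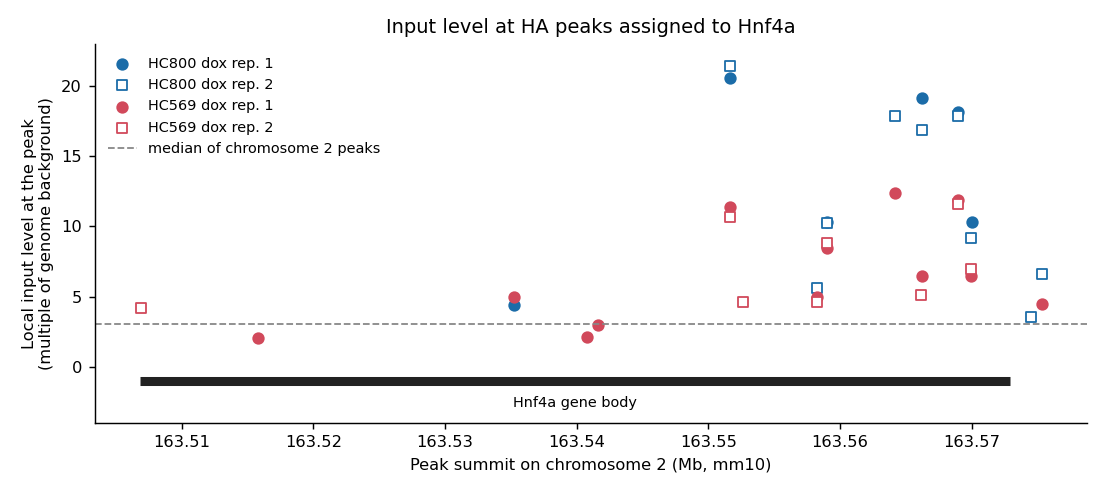
Local input level, as a multiple of the genome background, at each HA peak assigned to Hnf4a along chromosome 2 (Mb); colours are lines, symbols are replicates and the dashed line is the median of chromosome 2 peaks. Input reaches 21.5 in HC800 replicate 2, at a peak inside the gene.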

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

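The tests of the window correlation, balanced windows, swapped lines and other splits of the lists were chosen only after the result was seen. The settings with a common tag number, regions away from gene ends and matching on input were also chosen after seeing the data, with their bounds written before their values were known.

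Between the lines, 3 results differed in a test of the difference. Mesenchymal and EMT genes lay near HC800-only rather than HC569-only regions by 5 genes, and epithelial junction and keratin genes by −6. The gene-end share of HC800-only against HC569-only regions had an odds ratio of 2.63.

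The list differences were weighed against input level, depth and gene ends. With random lists matched also on window input, the unadjusted permutation p was 0.0006 for EMT and 0.0040 for epithelial genes. At a common tag number it was 0.0020 and 0.0048, and over regions more than 1 kb from a gene end 0.0156 and 0.0006. These lists had been picked because they passed. The values argue against copy number, depth or gene ends as the whole cause of either, with limits. The EMT call ended after adjustment in the last setting (adjusted permutation p = 0.0585, range over alternatives 0.0075 to 0.545), as the difference went from 5 to 3 genes against random means of −0.795 and −0.849. The epithelial call ended with equal peak numbers. Input matching was coarse, in classes cut at 0.2 (log2) to either side of balance. Neither copy number nor depth is excluded as part of the cause. For the line-only regions as a whole, copy number is a candidate source of part of them, since their ratio followed local input (r = 0.723), but not of all, since windows of balanced input still held 18.4 line-only regions per 100 shared regions against 20.2 overall. A difference between single libraries cannot be told apart from one between the lines: of the 3 splits of the 4 lists, too few for a share under 0.05, the split by line gave 2 lists and the highest other gave 2 as well, and the epithelial difference turned to +5 without replicate 1. A difference in cell state between the lines stays open and was not tested.

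The gene-end share differs along the crossed pairs of libraries. Regions called in HC800 replicate 2 and HC569 replicate 1 alone had a gene-end share of 9.91%, against 47.3% for HC800 replicate 1 and HC569 replicate 2 alone (Fisher's exact test over regions, odds ratio 8.16), and the odds ratio between the lines fell to 0.417 without replicate 1. Depth runs along the same pairs, with 30.4 and 19.0 M ChIP tags in HC800 replicate 2 and HC569 replicate 1. The other pair had 15.9 M in HC800 replicate 1 and 16.2 M in HC569 replicate 2. Depth as the source would have removed most of the 2219 regions of the first kind at a common tag number, but 1872 were left, with a gene-end share of 9.46%. That step scaled called peaks by a constant and did not redraw tags, so it cannot exclude depth as part of the source. Swapped lines in one replicate number are argued against by the pileup ratios of the 4 pairs across lines, which followed the input ratio of the lines with r of at least 0.861 over 199 windows. Also open, with no test here, is a difference in chromatin preparation or immunoprecipitation between libraries. No biological explanation was tested, since the crossed pairs match no group of the design.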

How the results depend on the processing

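Lists at a common tag number, regions more than 1 kb from a gene end, lists matched on input and crossed numbers were chosen after seeing the data. A threshold of 5 on −log10 q removed no peak (lowest value 7.70), so its outcome was fixed and it is no check. Within-line overlaps and shares at gene ends and in gene bodies stayed above the highest random placement under every other alternative run. Those alternatives used fewer placements than the 100 of the main test, too few for a permutation p under 0.05. Shared region counts carry no test and were compared by size only. The control peak overlapped all 4 lists with summits within 100 bp as well. The planned motif alternatives were not run. Unless stated, the cause was not tested. With a fold of at least 10, peaks numbered 14690 and 6911 in HC800, 13425 and 11719 in HC569 and 0 in the HC569 control.

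The labels share replicate numbers across lines, but regions of equal number did not deviate together (r = −0.21 for fold, −0.29 for pileup). Counted within each replicate number (replicate block), which drops the demand for both replicates, at least 7321 regions were HC800-only and 5536 HC569-only. With crossed numbers at least 4956 regions were HC800-only and at least 4746 HC569-only. These lowest counts came from different crossed pairs, so they do not belong to the same comparison. Leaving out a replicate number is the same calculation as counting within the other number, and is no separate check. It gave 7321 to 8265 HC800-only and 5536 to 10235 HC569-only regions. At a common tag number 596 were HC800-only and 1897 HC569-only.

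The odds ratio of a gene end between line-only sets ranged from 0.417 to 3.37 when a replicate number was left out. Shared regions beyond 1 kb of a gene end gave 2 lists past the threshold in place of 10. With smaller counts the other lists that lost their call stayed on their side of the random mean (classical subtype 1 against 3.36, cell cycle 9 against 3.82), except that the intestinal list turned to 5 genes against a random mean of 4.58 (adjusted permutation p = 1.0, range over alternatives 0.0094 to 1.0). For HC800-only regions 4 lists passed without replicate 1 and 4 without replicate 2, in place of 0, and the epithelial list held 8 to 13 genes when a replicate number was left out, in place of 0. For HC569-only regions 1 list passed in place of 2 with −log10 q of at least 10, unmatched random lists, equal peak numbers, a common tag number, matching on input or without replicate 1, and 2 without replicate 2. For the difference between lines, in place of 2, 1 list passed within 10 kb, 3 with −log10 q of at least 10 (Six1-type factors added, adjusted permutation p = 0.0285), 3 at a common tag number (endodermal factors added) and 1 to 4 when a replicate number was left out, where the epithelial difference ran from −11 to +5. Beyond 1 kb of a gene end 2 passed, the cell cycle list in place of EMT (adjusted permutation p = 0.0375), and with equal peak numbers 2, endodermal factors in place of epithelial genes. Depth limits the control lists most, as their inputs hold 0.649 and 5.30 M tags.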

Other observations

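Of the tests in this part, those of input level at Hnf4a had bounds written before their values were known; the genes with most regions or highest input and the crossed list counts were looked at after the data were seen.

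By number of shared regions, not set against gene length, Gse1 on chromosome 8 came first with 33, with folds of its strongest peaks from 27.9 to 64.4. Zmiz1 had 16, Ncor2, a nuclear receptor corepressor gene, 15, Septin9 14, and Gramd4 and the laminin gene Lama5 12 each (31.0 to 45.6 for Lama5). Rara, encoding a retinoic acid receptor, had 9 (17.2 to 32.2) and Cebpb, a factor of liver and fat, 9 within reach of a gene body of 1.52 kb (30.6 to 41.6). Plec, a cytolinker gene, had 10.

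Regions called in HC800 replicate 2 and HC569 replicate 1 alone lay near 10 of the 30 fatty acid and lipid genes and those of HC800 replicate 1 and HC569 replicate 2 alone near 0 (difference −10, adjusted permutation p = 0.0030). For epithelial junction and keratin genes the counts were 7 and 0 (adjusted permutation p = 0.0105). Both replicate 2 lists held 6 peaks on the mitochondrial chromosome, with folds of 1.63 to 7.23, and both replicate 1 lists held 0.

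Hnf4a ranked 3 of 371 genes with at least 3 shared regions in their body by local input in the lower of the 2 lines, at a median of 18.0 times background in HC800 and 8.61 times in HC569, behind Sfi1 (50.9 and 52.5) and Tmem267 (11.8 and 17.9). Integrated copies of the HNF4A cDNA may account for this, and would raise input inside the gene and not beside it. Input at peaks inside the gene was 4.43 times that at peaks within 1 Mb in HC800 and 2.39 times in HC569. The second value lies between the bounds set beforehand, 3 for and 1.5 against, and without exon coordinates the question stays undecided. Amplification of the chromosome segment is argued against, since input at peaks of other genes within 1 Mb was 1.03 times the chromosome 2 median in HC569 as a mean of its lists, the higher of the lines, and at most 1.07 times in a single list, while an amplified segment of the gene alone stays open and no biological explanation was tested.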
